A study of Mus musculus with 6 samples.

How the data were processed

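RNA was sequenced from C2C12 cells, an immortalised mouse myoblast line, harvested 48 h after the switch to differentiation medium, per the labels' protocols. The 6 libraries fall into 3 groups of 2: a scrambled shRNA, an shRNA against BAF250A and an shRNA against BRD9, each stably introduced. The series design text calls the 2 libraries of a group biological duplicates and says that a sequencing company made the libraries, sequenced them and did the downstream analysis. The labels give total RNA as the extracted molecule, and how messenger RNA was selected is not given in the sources used here. An shRNA against BAF180 is named in the treatment protocol, and its libraries were not analysed here.

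The material used here is 2 comparison tables made by the authors, one per knockdown, each with 27179 genes. The submitters' processing notes name HISAT, StringTie, Bowtie, RSEM and DESeq2 and the genome build mm10, with no role, order or version. Per the file headers, the deposited tables hold for each gene a mean normalized count, which is a signal averaged over the 4 libraries of the comparison after division by size factors. Per the file headers, the authors give a log2 fold change and its standard error on the same log2 scale. The Wald score, per the file headers, is the authors' log2 fold change divided by that error. Per the file headers, the authors also deposited a p-value of the Wald test and an adjusted p-value. The adjusted p-value equals a Benjamini-Hochberg adjustment over the genes that have one, as a recalculation from the deposited p-values showed. The tables do not state which group is the numerator. Positive values were read as higher in the knockdown, because Arid1a, the gene of BAF250A, is negative in the BAF250A table and Brd9 is negative in the BRD9 table. The targeted genes therefore set the sign and give no independent check of it, although the size of their change does bear on the labels.

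Values per library were not analysed here, so no count model was fitted and no spread between replicates was computed. The authors' Wald test and adjusted p below 0.05 were taken as deposited, which is the branch of the plan made for tables without counts. Because the labels call the libraries biological duplicates without saying how the cultures were separated, the p-values measure the spread between 2 libraries per group. The median standard error among genes with a mean normalized count of 100 or more was 0.48 for BAF250A and 0.54 for BRD9 on the log2 scale. The total count per library was not analysed here. Relative depth was recovered for the lowest genes, because a mean normalized count is a sum of whole reads times a fixed step per library. All genes with a mean below 3 (4629 in the BAF250A table and 4508 in the BRD9 table) resolved into whole reads of 4 libraries within a tolerance of 2e-08. The steps give size factors of 1.58 and 1.09 for the controls and 0.801 and 0.773 for the knockdown libraries of the BAF250A table. The BRD9 table gives 1.48 and 1.07 for the controls and 0.841 and 0.782 for the knockdown libraries. A library was taken as a control where genes with a single read in it had a negative fold change. Which of the libraries A and B has which size factor is unknown. The control reads were identical in 4076 of 4076 genes resolved in both tables, so both comparisons share the same 2 control libraries.

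For each gene the group means were computed from the authors' mean normalized count and log2 fold change, assuming that the fold change is the ratio of the 2 group means, and they are called implied means below. Genes with a single read, held by a control library, had a median log2 fold change of -0.19 with BAF250A and -0.18 with BRD9. A ratio of group means would be far lower there, so the assumption fails at the lowest counts. Low implied means are therefore uncertain. The difference between the knockdowns was tested as the difference of the deposited log2 fold changes divided by the square root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment over the 16311 genes tested in both tables. The shared controls cancel in this difference, so its true variance is smaller than assumed and the test is conservative. On simulated data for this comparison with 16311 genes, it recovered 12% of 50 genes that differed by 2 log2 units, 78% at 3, 98% at 4 and 100% at 5, and it called 0 unchanged genes. Overlaps between the knockdowns were set beside the product of the call numbers divided by the genes tested, and beside 100 simulations of unchanged groups that share their controls.

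The 27 gene lists were fixed before the data were examined. They are the targeted subunits, BAF-specific, PBAF-specific, ncBAF-specific and shared SWI/SNF subunits (members of more than 1 form, not all of them in ncBAF), myogenic regulators, sarcomere, myoblast fusion, excitation-contraction coupling and neuromuscular junction, muscle energy metabolism, cell cycle, cell cycle exit, undifferentiated and reserve cells, extracellular matrix, TGF-beta and YAP targets, smooth muscle, osteoblast, adipocyte, other cell types, interferon response, unfolded protein and integrated stress response, p53 targets, oxidative phosphorylation, glycolysis, cholesterol biosynthesis, ribosomal proteins and mitochondrially encoded genes. The 24 lists with 5 or more measured members were tested with cameraPR of limma 3.58.1 on the Wald score with a preset correlation of 0.01, which compares a list with all other genes. The 48 tests of the 2 knockdowns were adjusted together by Benjamini-Hochberg, and the tests of the difference separately. In 200 simulated runs of the difference, a sarcomere list shifted by 1 SD was called in 100%. The unshifted lists of glycolysis, cholesterol biosynthesis and interferon response were called in 0%. Genes were drawn independently in these runs, so they do not show the rate of false calls for lists of correlated genes. A correlation cannot be estimated without values per library, so 0.05 was tried in its place.

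The genes named in the text follow a rule fixed before the data were examined. It takes Arid1a, Brd9 and Pbrm1, then the 5 largest increases and 5 largest decreases per comparison among genes with an adjusted p below 0.05 and a mean normalized count of 100 or more (in both tables for the difference), leaving out provisional gene symbols. From each list it takes up to 3 called members with the smallest adjusted p, or up to 2 by unadjusted p where no member was called, and always Myod1, Myog, Mymk, Mymx, Myh3 and Ckm. Some genes that the rule takes are not reported here by name, and they stay in the counts and medians of their lists. Other genes are named only where the text says that they were chosen after their values were seen.

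Gene coordinates are those of RefSeq on GRCm38.p6, the assembly that mm10 names, and 25275 genes (93.0%) were matched by gene identifier. Sequence shared between genes was measured on GENCODE transcripts as the percent of a gene's 50-base words that also occur in another gene. Fold changes of genes with a high percent are uncertain, since the authors' counting could split reads among copies, and whether the counting used strand is not given in the sources used here. After seeing the data, the comparisons were repeated on protein-coding genes with under 5% shared words (16833 genes), and the difference test with the summed variance divided by 2. The alternatives planned before the data were examined were other thresholds, minimum fold changes, filters on the mean count, Bonferroni adjustment, centring on the median fold change, an empirical null, a second correlation, a rank-based list test and the fold change as list statistic. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.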

Results

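Gene expression was measured by RNA sequencing in C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into myotubes in low serum, 48 h after differentiation was induced with horse serum and insulin. Stable lines carried a scrambled shRNA, an shRNA against BAF250A or an shRNA against BRD9. BAF250A, encoded by Arid1a, belongs to the BAF form of the SWI/SNF chromatin remodelling enzymes, and BRD9 belongs to the ncBAF form. Each of the 3 groups had 2 libraries, and each knockdown was compared with the scrambled shRNA. The title of the series names the question, which is whether BAF and ncBAF are needed differently in muscle differentiation. All fold changes of single genes are the authors' log2 values of knockdown over scrambled shRNA with their deposited standard errors (SE), and spreads between libraries were not analysed here. The smallest log2 fold change called at an adjusted p below 0.05 in the authors' deposited tables was 1.02 in size for BAF250A and 1.29 for BRD9, so smaller changes were not detectable at this precision.

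The targeted gene was lower in each knockdown, though neither call held under the empirical null. Arid1a (gene 93760, a protein-coding gene at 133679008 to 133756769 on chromosome 4 of mm10) fell by 1.95 (SE 0.48) in BAF250A knockdown in the authors' deposited table, to 25.8% of the control level, with an adjusted p of 0.00038 by the Wald test. Its value in BRD9 knockdown was -0.17 (SE 0.52), which did not pass the test in the authors' deposited table. Brd9 (gene 105246, a protein-coding gene at 73937801 to 73960895 on chromosome 13 of mm10) fell by 1.60 (SE 0.54) in BRD9 knockdown in the authors' deposited table, to 33.0% of control, with an adjusted Wald p of 0.0252. It stood at 0.16 (SE 0.44) in the authors' deposited table for BAF250A. Pbrm1, which encodes BAF180 (gene 66923, at 31019138 to 31121592 on chromosome 14), stood at 0.52 (SE 0.57) and -0.19 (SE 0.62) in the authors' deposited tables for BAF250A and BRD9 and passed neither test. Between the knockdowns, Arid1a and Brd9 differed by -1.79 and 1.76, with adjusted p of 0.246 and 0.242 by the difference z test with Benjamini-Hochberg adjustment, and both passed when adjusted over the list alone (2 genes).

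Few other subunits were called. Smarce1, which encodes a subunit of BAF and PBAF, rose by 1.49 (SE 0.42) and 1.59 (SE 0.48) in the authors' deposited tables for BAF250A and BRD9, with 15% of its words shared with another gene. The ATPase gene Smarca2 rose by 1.56 (SE 0.50) and 1.49 (SE 0.55) in the authors' deposited tables, and these 2 were the called members among 15 measured shared subunits in each knockdown (also 2 adjusted over the list alone). Phf10, a PBAF subunit gene, rose by 1.46 (SE 0.45) with BAF250A in the authors' deposited table and was the 1 called member of 4. With BRD9 0 of the 4 passed, and Brd7 stood at 1.01 (SE 0.50) and Phf10 at 0.92 (SE 0.52) in the authors' deposited table. Of the 5 BAF-specific genes Arid1a alone was called in BAF250A knockdown and 0 in BRD9 knockdown, where Dpf3 stood at -1.58 (SE 1.29) in the authors' deposited table. Of the 3 ncBAF-specific genes 0 were called in BAF250A knockdown, with Bicra at -0.61 (SE 0.44) and Bicral at 0.59 (SE 0.50) in the authors' deposited table, and Brd9 alone in BRD9 knockdown. Adjustment over the list alone gave the same counts for these lists in each knockdown. In cameraPR with Benjamini-Hochberg adjustment the shared subunits had adjusted p of 0.157 (BAF250A) and 0.0612 (BRD9), and the BAF-specific genes 0.54 and 0.988, the last with a median of -0.15 although the test pointed up.

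In BAF250A knockdown, genes of muscle contraction were far lower than with scrambled shRNA, and some fusion genes fell while the fusion list did not pass its test. Myh3, the embryonic myosin heavy chain (gene 17883, at 67078273 to 67102291 on chromosome 11 of mm10), fell by 4.38 (SE 0.44) in the authors' deposited table, from an implied mean of 64009 to 3070 normalized counts. Mymk, the fusion protein myomaker (gene 66139, at 27061636 to 27072161 on chromosome 2), fell by 4.86 (SE 0.51) in the authors' deposited table. Ckm, muscle creatine kinase (gene 12715, at 19411094 to 19421583 on chromosome 7), fell by 5.24 (SE 0.55) in the authors' deposited table. Myog, the myogenic regulator myogenin (gene 17928, at 134290004 to 134292548 on chromosome 1), fell by 1.94 (SE 0.53) with an adjusted Wald p of 0.00156 in the authors' deposited table. The regulator Myod1 (gene 17927, at 46376474 to 46379092 on chromosome 7), at 0.97 (SE 0.47), and the fusion peptide gene Mymx, at -1.24 (SE 0.56), did not pass, with adjusted Wald p of 0.106 and 0.0818 in the authors' deposited table.

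Of 45 measured sarcomere genes, 0 rose and 39 fell in BAF250A knockdown (42 adjusted over the list alone), with a median log2 fold change of -3.16 and an adjusted cameraPR p of 4.4e-24. Among them Myl4, an embryonic myosin light chain, fell by 5.69 (SE 0.57) in the authors' deposited table. Of 24 genes of excitation-contraction coupling and the neuromuscular junction, 19 fell and 0 rose (20 adjusted over the list alone), with a median of -1.95 and an adjusted cameraPR p of 8.8e-08. The calsequestrin gene Casq2 fell by 4.66 (SE 0.49), the calcium channel gene Cacna1s by 3.38 (SE 0.49) and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 3.05 (SE 0.44) in the authors' deposited table. Of 16 genes of muscle energy metabolism, 7 fell and 1 rose over all genes and adjusted over the list alone, with a median of -1.14. The adjusted cameraPR p of this list was 0.0496, and 0.141 with the correlation set to 0.05. Cox8b, a cytochrome oxidase subunit, fell by 9.50 (SE 0.86) to an implied mean of 2.84 normalized counts, and the muscle glycogen phosphorylase gene Pygm by 2.36 (SE 0.51), in the authors' deposited table. Of 18 myogenic regulators 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -1.09 and an adjusted cameraPR p of 0.218, or 0.0136 among genes with little shared sequence, a setting chosen after seeing the data. Ankrd2, a stretch-responsive muscle gene, fell by 3.89 (SE 0.56) and the transcription factor gene Tead4 by 2.75 (SE 0.48) in the authors' deposited table. The growth factor gene Igf2 rose by 2.22 (SE 0.43) in the authors' deposited table, an uncertain value because 61.2% of its words are shared with another gene. Of 16 fusion genes 6 fell and 1 rose, also when adjusted over the list alone, with a median of -0.66 and an adjusted cameraPR p of 0.203 (0.0443 among genes with little shared sequence). The caveolin gene Cav3 fell by 5.32 (SE 0.55) and the M-cadherin gene Cdh15 by 1.43 (SE 0.46) in the authors' deposited table.

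Genes of the extracellular matrix, smooth muscle and sterol synthesis were higher in BAF250A knockdown, and interferon response genes were lower. Of 30 matrix genes 19 rose and 0 fell (21 adjusted over the list alone), with a median of 2.05 and an adjusted cameraPR p of 4.7e-15. The fibrillar collagen genes Col11a1, Col1a1 and Col1a2 rose by 10.02 (SE 0.67), 4.58 (SE 0.41) and 4.26 (SE 0.41) in the authors' deposited table. Of 10 smooth muscle genes 6 rose and 0 fell (7 adjusted over the list alone), with a median of 1.91 and an adjusted cameraPR p of 8.4e-05. Among these, Tagln (transgelin) rose by 3.47 (SE 0.42), Cnn1 (calponin) by 3.60 (SE 0.43) and Lmod1 (leiomodin) by 3.36 (SE 0.48) in the authors' deposited table. Of 14 TGF-beta and YAP targets 7 rose and 1 fell, also when adjusted over the list alone, with a median of 1.25 and an adjusted cameraPR p of 0.00565. They included the matrix protein gene Tgfbi at 2.93 (SE 0.46) and Amotl2 at 2.47 (SE 0.41) in the authors' deposited table. All 24 interferon response genes fell (24 adjusted over the list alone), with a median of -5.78 and an adjusted cameraPR p of 2.3e-49. Usp18, a protease that limits interferon signalling, fell by 10.35 (SE 0.68) in the authors' deposited table, from an implied mean of 10186 to 7.81 normalized counts. Ifi44 stood at -8.75 (SE 0.62) and Ifit3 at -10.25 (SE 0.51) in the authors' deposited table, Ifit3 with 51.2% of its words shared with another gene. Of 22 genes of cholesterol biosynthesis 15 rose and 0 fell, also when adjusted over the list alone, with a median of 1.89 and an adjusted cameraPR p of 6.5e-09. The synthesis enzyme gene Fdps, with 26.2% shared words, rose by 3.73 (SE 0.49) and the sterol sensor partner gene Insig1 by 2.60 (SE 0.44) in the authors' deposited table.

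Of 33 genes of oxidative phosphorylation 12 rose and 0 fell in BAF250A knockdown, also when adjusted over the list alone (median 0.55, adjusted cameraPR p of 1.5e-04). In the 27 members with little shared sequence 7 rose, with a median of 0.30 and an adjusted cameraPR p of 0.029. Cox5b rose by 4.14 (SE 0.47), Ndufa4 by 3.64 (SE 0.42) and Atp5o by 4.29 (SE 0.50) in the authors' deposited table, Cox5b and Atp5o with 11.9% and 14.0% shared words. Of 16 glycolysis genes 5 rose and 0 fell, also when adjusted over the list alone (median 0.71, adjusted cameraPR p of 0.00221). The aldolase gene Aldoc stood at 5.65 (SE 0.55), Pfkfb3 at 2.44 (SE 0.44) and Pgk1, with 53.9% shared words, at 3.28 (SE 0.51) in the authors' deposited table. Of 34 cell cycle genes 6 rose and 3 fell, also when adjusted over the list alone (median 0.32, adjusted cameraPR p of 0.0928). The mitotic cyclin genes Ccnb1 and Ccnb2 rose by 2.22 (SE 0.43) and 1.35 (SE 0.42) and the replication clamp gene Pcna by 1.74 (SE 0.45) in the authors' deposited table, Ccnb1 and Pcna with 23.4% and 19.1% shared words. Among the 28 members with little shared sequence 3 rose and 3 fell, with a median of 0.09. Among 8 genes of cell cycle exit, 1 rose and 1 fell, also when adjusted over the list alone (median 0.60, adjusted cameraPR p of 0.0696). The kinase inhibitor gene Cdkn1c rose by 6.49 (SE 0.52) and Cdkn1a fell by 1.93 (SE 0.49) in the authors' deposited table. Of 18 genes of undifferentiated and reserve cells 5 rose and 0 fell, also when adjusted over the list alone (median 0.49, adjusted cameraPR p of 0.0612). They included the inhibitors of myogenic factors Id3 at 2.48 (SE 0.45) and Id2 at 2.81 (SE 0.52) and the repressor gene Snai1 at 1.69 (SE 0.46) in the authors' deposited table. In the stress response list 3 of 16 rose and 1 fell, also when adjusted over the list alone (median 0.53, adjusted cameraPR p of 0.273). Among these 4 were Asns at 1.65 (SE 0.44), Phgdh, with 47.8% shared words, at 1.84 (SE 0.51) and Atf3 at -3.29 (SE 0.47) in the authors' deposited table. Of 15 p53 targets 1 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.53, adjusted cameraPR p of 0.885). Sesn1 stood at 1.87 (SE 0.44) and the nuclease gene Aen at -1.28 (SE 0.46) in the authors' deposited table. Among 13 mitochondrially encoded genes ND6 alone was called, at -1.63 (SE 0.42) in the authors' deposited table, also when adjusted over the list alone. The list's median of -0.06 went against a test that pointed up (adjusted cameraPR p of 0.972).

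Markers of other lineages moved both ways in BAF250A knockdown. Of 10 osteoblast genes 2 rose and 3 fell, also when adjusted over the list alone (median 0.66, adjusted cameraPR p of 0.396). The growth factor gene Bmp4 stood at 3.84 (SE 0.46), Alpl at 2.78 (SE 0.70) and Dlx3 at -2.16 (SE 0.43) in the authors' deposited table. Of 7 adipocyte genes 1 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.76, adjusted cameraPR p of 0.772). The lipase gene Lpl stood at 1.51 (SE 0.55) and Plin4 at -3.29 (SE 0.63) in the authors' deposited table. Of 9 markers of macrophages, endothelium, epithelium and neurons 1 rose and 3 fell, also when adjusted over the list alone (median -0.77, adjusted cameraPR p of 0.496). They were Lyz2, with 15.4% shared words, at 4.18 (SE 0.92), Kdr at -7.60 (SE 1.16), Map2 at -3.45 (SE 0.72) and, named after its value was seen, Cd68 at -2.53 (SE 0.60) in the authors' deposited table.

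Across all 16450 genes tested with BAF250A, 4729 were called by the authors' Wald test in the authors' deposited table, 1844 higher and 2885 lower. Among genes with a mean normalized count of 100 or more and no provisional symbol, the largest increases were in the retinoic acid binding protein gene Crabp1 at 10.76 (SE 0.70), Col11a1, the ribosomal protein gene Rps29 at 9.29 (SE 0.46), the chemokine gene Cxcl14 at 9.06 (SE 1.09) and the transcription factor gene Foxd1 at 8.83 (SE 1.10) in the authors' deposited table. The largest decreases among them were in Aldoart2 at -13.71 (SE 0.95), Ndufa11b at -12.46 (SE 0.98), Aldoart1 at -12.17 (SE 0.57), Prdx6b at -11.97 (SE 0.99) and Atp5c1-ps at -11.56 (SE 1.00) in the authors' deposited table. Aldoart1 and Aldoart2 are retrotransposed copies of an aldolase gene. Their sizes are uncertain because implied means on the low side were 0.634 normalized counts for Cxcl14 and 1.77 for Aldoart2. Restricted to protein-coding genes with little shared sequence, a setting chosen after seeing the data, 2817 genes were called, 1361 higher and 1456 lower. All protein-coding genes together held 1816 of the higher and 1958 of the lower calls. Bonferroni adjustment left 1565 and an empirical null 693.

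In BRD9 knockdown, Myh3, Mymk, Ckm, Myog and Mymx did not pass the test, and some other muscle genes rose. Myh3 stood at 0.41 (SE 0.51), Mymk at -0.04 (SE 0.55), Ckm at -0.58 (SE 0.58), Myog at 0.83 (SE 0.57) and Mymx at 1.48 (SE 0.59) in the authors' deposited table. None passed the Wald test, with adjusted p from 0.0729 (Mymx) to 0.98 (Mymk). Myod1 rose by 1.67 (SE 0.53), with an adjusted Wald p of 0.0142 in the authors' deposited table. Of 45 sarcomere genes 6 rose and 2 fell, also when adjusted over the list alone, with a median of 0.27. The cardiac actin gene Actc1 rose by 2.20 (SE 0.52) and the alpha-actinin gene Actn2 by 2.53 (SE 0.63) while Myl4 fell by 2.53 (SE 0.62) in the authors' deposited table. The adjusted cameraPR p was 0.033 upward, with adjusted p = 0.193 at a correlation of 0.05 and 0.137 among genes with little shared sequence, so the call of this list was lost in both. The median of its 39 members with little shared sequence was again 0.27.

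Among 26 genes of excitation-contraction coupling and the neuromuscular junction 3 rose and 0 fell in BRD9 knockdown, also when adjusted over the list alone (median 0.75, adjusted cameraPR p of 0.0188 and 0.107 at a correlation of 0.05). The sodium channel gene Scn4a rose by 2.20 (SE 0.54), Stac3 by 2.17 (SE 0.54) and Dok7, an activator of the junction's receptor kinase, by 1.84 (SE 0.56) in the authors' deposited table. Of 18 myogenic regulators 4 rose and 2 fell, also when adjusted over the list alone (median 0.63, adjusted cameraPR p of 0.0251, 0.105 at a correlation of 0.05 and 0.0579 with little shared sequence, where the median was 0.44). The RNA-binding protein gene Rbm24 stood at 4.78 (SE 0.51), Megf10 at 1.81 (SE 0.54) and Igf2 at 2.29 (SE 0.55) in the authors' deposited table. Of 16 fusion genes 3 rose and 0 fell (4 adjusted over the list alone; median 0.54, adjusted cameraPR p of 0.0251, and 0.100 at a correlation of 0.05). They were the dysferlin gene Dysf at 1.78 (SE 0.52), Tspan33 at 2.02 (SE 0.60) and the adhesion gene Jam3 at 1.38 (SE 0.48) in the authors' deposited table. In muscle energy metabolism 4 of 18 rose and 1 fell (4 and 2 adjusted over the list alone; median 0.55, adjusted cameraPR p of 0.181). The glucose transporter gene Slc2a4 stood at 2.97 (SE 0.76), Ampd1 at 3.12 (SE 0.92) and Cox8b at -2.93 (SE 0.67) in the authors' deposited table. Of 18 genes of undifferentiated and reserve cells 5 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.85, adjusted cameraPR p of 5.9e-04). Pax7, the regulator of muscle stem cells, rose by 4.26 (SE 0.53), and the Notch target genes Heyl and Hey1 by 2.95 (SE 0.51) and 2.60 (SE 0.57), in the authors' deposited table. Of 8 genes of cell cycle exit Cdkn1c alone was called, up by 9.71 (SE 0.54) in the authors' deposited table (2 adjusted over the list alone; median 0.48, adjusted cameraPR p of 0.00111). The list test uses the mean score, in which Cdkn1c weighs heavily, and it was not repeated without this gene. Among 34 cell cycle genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.05, adjusted cameraPR p of 0.496). Pcna stood at 1.76 (SE 0.53), Ccnb1 at 1.42 (SE 0.51) and the kinetochore gene Cenpf at -1.94 (SE 0.59) in the authors' deposited table. Among the 28 members with little shared sequence 0 rose and 1 fell, with a median of -0.10.

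Matrix and sterol genes were higher and interferon response genes lower with BRD9 knockdown too. Of 30 matrix genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.39 and an adjusted cameraPR p of 5.3e-08. Col11a1 rose by 6.04 (SE 0.76), the gelatinase gene Mmp2 by 3.78 (SE 0.53) and Col6a1 by 3.42 (SE 0.49) in the authors' deposited table. Of 22 genes of cholesterol biosynthesis 15 rose and 0 fell (16 adjusted over the list alone), with a median of 1.72 and an adjusted cameraPR p of 1.0e-09. Fdps rose by 3.25 (SE 0.54) and Insig1 by 2.84 (SE 0.50) in the authors' deposited table. Of 24 interferon response genes 22 fell and 0 rose (23 adjusted over the list alone), with a median of -4.46 and an adjusted cameraPR p of 1.7e-41. The antiviral synthetase gene Oas2 stood at -7.81 (SE 0.59), Usp18 at -7.60 (SE 0.61) and Ifit3 at -6.36 (SE 0.51) in the authors' deposited table. In oxidative phosphorylation 9 of 33 rose and 0 fell (11 adjusted over the list alone; median 0.52, adjusted cameraPR p of 6.9e-05). In the 27 members with little shared sequence 5 rose, with a median of 0.19 and an adjusted cameraPR p of 0.0177. Cox5b stood at 4.01 (SE 0.51), Atp5o at 4.17 (SE 0.55) and Ndufa4 at 3.57 (SE 0.48) in the authors' deposited table. Of 16 glycolysis genes 2 rose and 1 fell, also when adjusted over the list alone (median 0.12, adjusted cameraPR p of 0.273), namely Aldoc at 4.04 (SE 0.68), Pgk1 at 1.85 (SE 0.55) and Gapdh, with 24.7% shared words, at -1.89 (SE 0.50) in the authors' deposited table.

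Of 14 TGF-beta and YAP targets 0 rose and 2 fell in BRD9 knockdown, also when adjusted over the list alone. They were the activin gene Inhba at -2.88 (SE 0.58) and the matricellular gene Ccn2 at -2.58 (SE 0.58) in the authors' deposited table. The list's median of -0.07 went against a test that pointed up (adjusted cameraPR p of 0.988). Of 10 smooth muscle genes Lmod1 alone was called, at 2.21 (SE 0.55) in the authors' deposited table (2 adjusted over the list alone; median 0.37, adjusted cameraPR p of 0.133). In the stress response list 0 of 16 rose and 3 fell (4 adjusted over the list alone). These were Atf3 at -2.92 (SE 0.53), Ddit3 at -2.60 (SE 0.55) and Chac1 at -1.54 (SE 0.52) in the authors' deposited table. The median of 0.12 went against a test that pointed down (adjusted cameraPR p of 0.611). Of 15 p53 targets 1 rose and 1 fell, also when adjusted over the list alone (median -0.51, adjusted cameraPR p of 0.749). Sesn1 stood at 1.65 (SE 0.50) and Phlda3 at -1.54 (SE 0.55) in the authors' deposited table. Of 13 mitochondrially encoded genes 0 were called (0 adjusted over the list alone; median 0.43, adjusted cameraPR p of 0.119). ATP8 stood at 1.34 (SE 0.52) and ND4L at 1.19 (SE 0.50) in the authors' deposited table. Of 10 osteoblast genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.28, adjusted cameraPR p of 0.988). They were Dmp1 at 2.60 (SE 0.59) and the near-identical osteocalcin genes Bglap and Bglap2 at -3.17 (SE 1.07) and -2.20 (SE 0.65) in the authors' deposited table, the osteocalcin values uncertain for shared reads. Of 7 adipocyte genes Plin4 alone was called, at -1.89 (SE 0.62) in the authors' deposited table (1 higher and 3 lower adjusted over the list alone). Its list had a median of 0.21 against a test that pointed down (adjusted cameraPR p of 0.913). Of 11 markers of other cell types 1 rose and 2 fell, also when adjusted over the list alone. Map2 stood at 1.96 (SE 0.73), Kdr at -5.32 (SE 0.78) and Cd68 at -2.46 (SE 0.62) in the authors' deposited table. Here too the median of 0.36 went against a test that pointed down (adjusted cameraPR p of 0.92).

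Across all 17198 genes tested with BRD9, 2483 were called by the authors' Wald test in the authors' deposited table, 879 higher and 1604 lower. Under the same limits of mean count and symbol, the largest increases were in Cdkn1c, Rps29 at 8.54 (SE 0.51), the muscle peptidase gene Ky at 7.90 (SE 1.02), Rps21 at 7.43 (SE 0.54) and Atp5md at 7.20 (SE 0.53) in the authors' deposited table. The largest decreases under these limits were in Aldoart2 at -13.24 (SE 0.86), Prdx6b at -11.54 (SE 0.89), Aldoart1 at -11.38 (SE 0.58), Atp5c1-ps at -11.14 (SE 0.90) and Ndufa11b at -10.98 (SE 0.74) in the authors' deposited table. These are the 5 genes named above for the largest decreases with BAF250A. Restricted to protein-coding genes with little shared sequence, 949 genes were called, 496 higher and 453 lower. All protein-coding genes together held 870 of the higher and 876 of the lower calls, so the excess of lower calls lay in other kinds of genes. Bonferroni adjustment left 940 and an empirical null 873.

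The difference between the knockdowns was tested gene by gene, and muscle genes were among its largest values. Myh3 differed by -4.79 (SE 0.68) between BAF250A and BRD9 knockdown on the log2 scale, Mymk by -4.82 (SE 0.75), Ckm by -4.66 (SE 0.80), Myog by -2.77 (SE 0.78) and Mymx by -2.72 (SE 0.81). All were lower with BAF250A, with adjusted p of 1.5e-09, 8.8e-08, 2.4e-06, 0.0182 and 0.0348 by the difference z test. Myod1 differed by -0.70 (SE 0.71) and did not pass (adjusted p of 1 by the difference z test). Of 45 sarcomere genes 34 were lower with BAF250A and 0 higher (41 adjusted over the list alone), with a median of -3.38 and an adjusted cameraPR p of 3.0e-98. The perinatal and fast myosin genes Myh8 and Myh4 differed by -7.45 (SE 0.86) and -7.30 (SE 0.95), Actn2 by -6.87 (SE 0.84) and Smpx, a small muscle protein, by -7.19 (SE 0.95). Myh8 and Myh4 share 12.1% and 18.9% of their words with other genes. The sizes for Myh4 and Smpx are uncertain, because their implied means in BAF250A knockdown were 3.07 and 3.69 normalized counts. Of 24 genes of excitation-contraction coupling and the neuromuscular junction 12 were lower with BAF250A (18 adjusted over the list alone; median -2.48, adjusted cameraPR p of 1.0e-38). Scn4a differed by -6.00 (SE 0.83), Casq2 by -5.12 (SE 0.73) and Cacna1s by -4.75 (SE 0.73). The fusion list had 6 of 16 lower (8 adjusted over the list alone; median -1.39, adjusted cameraPR p of 5.1e-09), with Cav3 at -4.61 (SE 0.80) and Tspan33 at -3.70 (SE 0.86). Of 18 myogenic regulators 6 were lower, also when adjusted over the list alone (median -0.88, adjusted cameraPR p of 7.7e-09), with Ankrd2 at -4.33 (SE 0.85), Rbm24 at -3.74 (SE 0.71) and Tead4 at -3.72 (SE 0.71). In muscle energy metabolism 4 of 16 were lower (6 adjusted over the list alone; median -0.78, adjusted cameraPR p of 2.0e-07), with Cox8b at -6.57 (SE 1.09) and Pygm at -3.18 (SE 0.78).

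**Figure D1:**
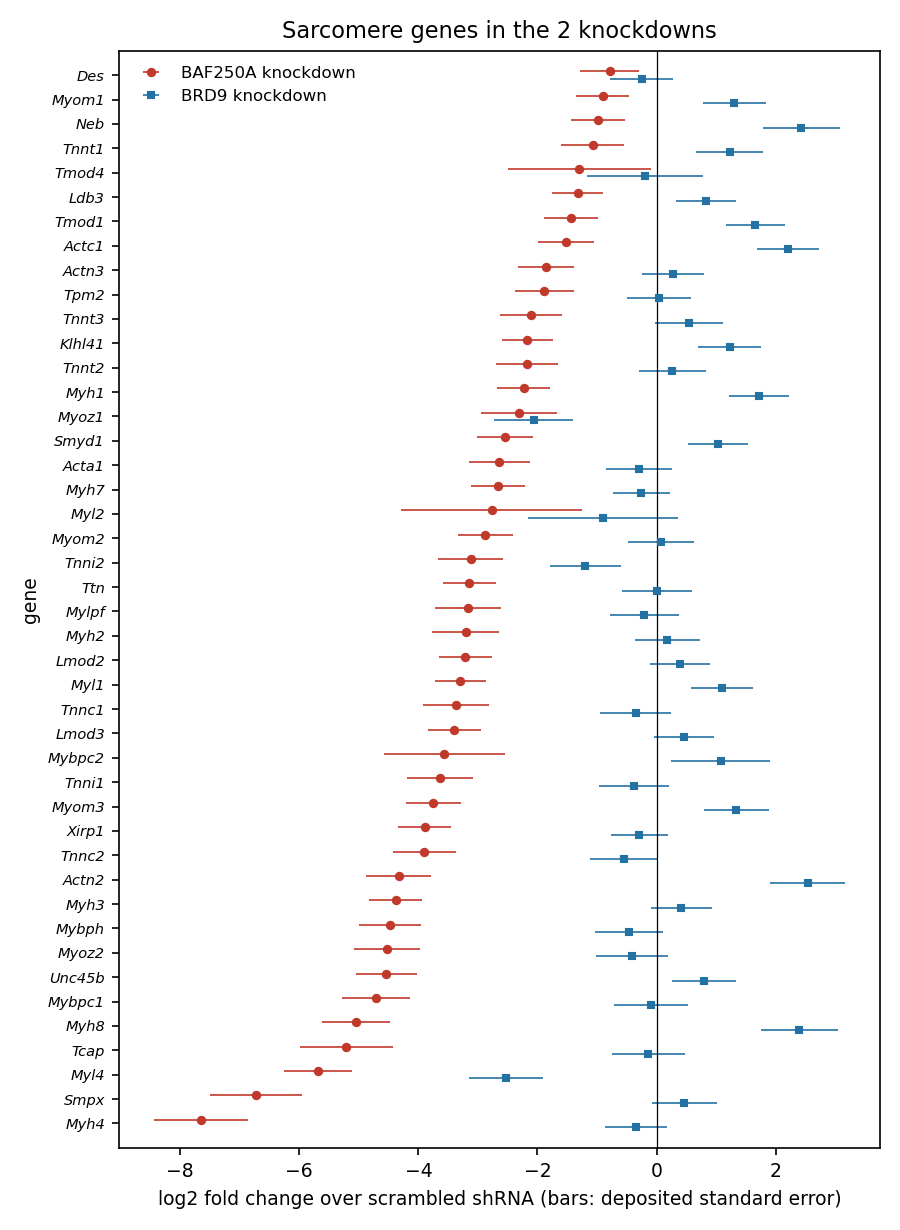
Log2 fold change over scrambled shRNA (horizontal axis) of the measured sarcomere genes, 1 left out (vertical axis), in BAF250A knockdown (red circles) and BRD9 knockdown (blue squares), with bars for the authors' deposited standard errors. Over all 45 measured genes the median is -3.16 with BAF250A and 0.27 with BRD9.

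The other groups that differed were higher with BAF250A, apart from interferon response genes, which were lower. Of 14 TGF-beta and YAP targets 2 were higher (5 adjusted over the list alone; median 1.03, adjusted cameraPR p of 6.2e-07), among them Inhba by 3.13 (SE 0.77). Of 30 matrix genes 2 were higher (6 adjusted over the list alone; median 0.70, adjusted cameraPR p of 7.2e-07), Col11a1 by 3.98 (SE 1.02) and the periostin gene Postn by 2.87 (SE 0.87). Of 10 smooth muscle genes Cnn1 alone was called, higher by 3.17 (SE 0.79) (2 adjusted over the list alone; median 1.42, adjusted cameraPR p of 1.3e-04). In glycolysis 0 of 16 genes were called (0 adjusted over the list alone; median 0.80, adjusted cameraPR p of 2.9e-04), with Pfkfb3 at 1.72 (SE 0.67) and Pgk1 at 1.43 (SE 0.75). The stress response list had 0 of 16 called (0 adjusted over the list alone; median 0.56, adjusted cameraPR p of 0.00116), with Chac1 at 2.05 (SE 0.70) and Trib3 at 1.91 (SE 0.75). Ribosomal protein genes had 0 of 38 called (0 adjusted over the list alone; median 0.51, adjusted cameraPR p of 0.00116), with Rps3 at 0.87 (SE 0.71) and Rpsa at 0.83 (SE 0.72). In the 5 members with little shared sequence the median was 0.50 and the call was lost (adjusted cameraPR p of 0.219). Of 34 cell cycle genes 1 was called, E2f2 at -2.24 (SE 0.69), also when adjusted over the list alone, against a median of 0.47 (adjusted cameraPR p of 0.0491, with adjusted p = 0.214 at a correlation of 0.05 and 0.091 with little shared sequence, where the median was 0.48). Interferon response genes were lower still with BAF250A than with BRD9, 4 of 24 by the difference z test (10 adjusted over the list alone; median -1.47, adjusted cameraPR p of 9.8e-11). Of these 4 calls 1 was among the 17 protein-coding members with little shared sequence, whose median was -1.41 (adjusted cameraPR p of 2.0e-05). Among the 4 were Ifit3 at -3.89 (SE 0.72), Ifit1 at -3.85 (SE 0.84) and Rsad2 at -4.48 (SE 1.00).

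The remaining lists that were tested with cameraPR did not differ between the knockdowns by it, and lists with under 5 measured members were not tested. Among reserve cell genes Heyl at -3.84 (SE 0.68) and Pax7 at -4.02 (SE 0.85) were lower with BAF250A (2 of 17; 4 lower and 1 higher adjusted over the list alone). The list had a median of -0.45 and an adjusted cameraPR p of 0.129. Cdkn1c differed by -3.21 (SE 0.75) and was the 1 called gene of 8 in cell cycle exit, also when adjusted over the list alone (median -0.23, adjusted cameraPR p of 0.231). Bmp4 was higher by 3.84 (SE 0.74), the 1 called osteoblast gene of 10 (adjusted cameraPR p of 0.155). Map2 differed by -5.42 (SE 1.02), the 1 called marker of other cell types among 9 (adjusted cameraPR p of 0.267). Adjusted over the list alone, both counts were also 1. No member was called for cholesterol biosynthesis (Hsd17b7 -0.95, SE 0.80, and Cyp51 0.67, SE 0.63) or oxidative phosphorylation (Cox7a2 1.15, SE 0.93, and Ndufa1 0.69, SE 0.72). The same held for p53 targets (Fas 1.51, SE 0.68, and Eda2r -1.11, SE 0.79) and mitochondrially encoded genes (ND2 -0.81, SE 0.68, and ND1 -0.64, SE 0.63). Their adjusted cameraPR p were 0.331, 0.416, 0.716 and 0.149, and 0 members were called adjusted over the list alone. The adipocyte list had 0 of 7 called (1 adjusted over the list alone, adjusted cameraPR p of 0.331), with Fabp4 at 4.09 (SE 1.32) and Plin4 at -1.40 (SE 0.88). Among the SWI/SNF lists 0 were called, with Dpf1 at -0.62 (SE 0.80), Pbrm1 at 0.72 (SE 0.84), Bicra at -0.30 (SE 0.66), Smarcd3 at -0.79 (SE 0.70) and Smarcc2 at -0.71 (SE 0.65). The adjusted cameraPR p was 0.245 for BAF-specific and 0.844 for shared subunits. Adjusted over the list alone, Brd9 was the 1 called ncBAF-specific gene, higher with BAF250A.

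Over the 16311 genes tested in both tables, 414 differed between the knockdowns by the difference z test, 90 higher and 324 lower with BAF250A, and 1362 had an unadjusted p below 0.05. Among genes with a mean normalized count of 100 or more in both tables and no provisional symbol, the largest differences toward BAF250A were in the interleukin-1 receptor antagonist gene Il1rn at 5.27 (SE 0.80), the lysophospholipase gene Enpp2 at 4.62 (SE 0.81), the growth factor gene Igf1 at 4.50 (SE 0.84), the pentraxin gene Ptx3 at 4.42 (SE 0.70) and Col11a1. Among the same genes, the largest toward BRD9 were in Myh8, Myh4, Smpx and Actn2, together with the transcription factor gene Msc (musculin) at -7.36 (SE 1.25). The sizes for Msc, Myh4 and Smpx are uncertain, because their implied means in BAF250A knockdown were 1.13, 3.07 and 3.69 normalized counts. The count was 123 after Bonferroni adjustment, 691 under an empirical null and 1231 with the summed variance divided by 2, the last chosen after seeing the data. With a correlation of 0.05 in place of 0.01 every cameraPR call above held except those whose second p is given. These are muscle energy metabolism with BAF250A, sarcomere, excitation-contraction coupling, myogenic regulators and fusion with BRD9, and cell cycle in the difference.

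Calls of the knockdowns overlapped beyond both reference values. Of the 16311 genes, 648 were higher in both tables, against 95.8 for independent lists of 1812 and 862 genes and 7.78 in 100 simulations of unchanged groups with shared controls. There were 1365 genes lower in both, against 284 for independent lists of 2885 and 1604 genes and 8.23 simulated. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.805 (0.494 simulated), with a covariance of 2.72 (0.261 simulated). Among the 12325 protein-coding genes with little shared sequence the correlation was 0.671 and the covariance 1.31 (0.223 simulated), with 319 genes higher and 347 lower in both, against 52.2 and 53.5 for independent lists. The simulations held only random variation of the shared controls, so they give no reference for a systematic difference between control and knockdown libraries. The 2 control libraries cannot be split, so an unknown part of the excess may come from the shared controls. In opposite directions 39 genes were called, 32 of them lower with BAF250A and higher with BRD9, among these Myh8, Actn2, Scn4a, Actc1, Dok7, Tspan33 and Dysf.

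**Figure D2:**
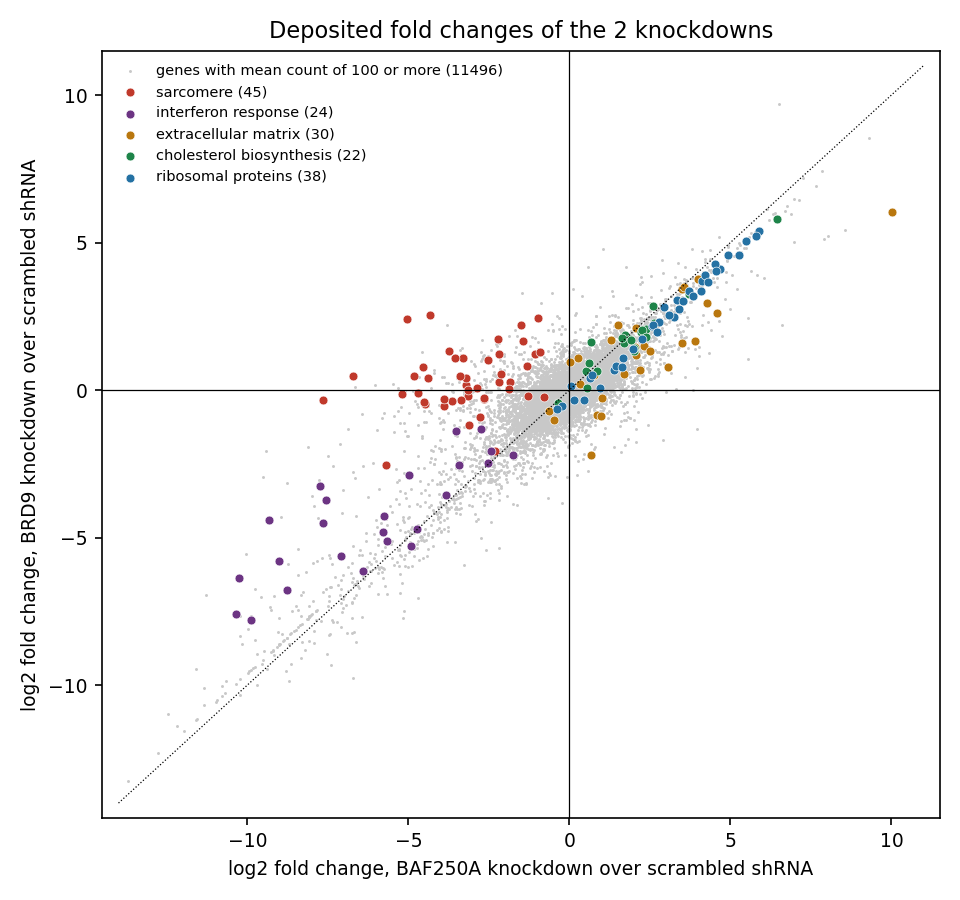
Log2 fold change over scrambled shRNA in BAF250A knockdown (horizontal axis) and BRD9 knockdown (vertical axis) for 11496 genes with a mean normalized count of 100 or more in both tables (grey points), with members of 5 gene lists coloured and the dotted line marking equal values. The sarcomere genes lie to the left of the line near a BRD9 value of 0, and the cholesterol biosynthesis genes have the smallest median difference of the 5 lists, 0.20.

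Part of what both tables held in common varied with sequence shared between genes. Ribosomal protein genes, most of which have near-identical pseudogene copies, were higher in both knockdowns. With BAF250A, 30 of 38 rose and 0 fell (median 3.01, adjusted cameraPR p of 3.1e-29), and with BRD9 26 of 38 rose and 0 fell (median 2.52, adjusted cameraPR p of 1.2e-27). Adjusted over the list alone, the numbers were again 30 and 26. Rpl12 rose by 5.89 (SE 0.48) and 5.38 (SE 0.52), Rpl37 by 5.78 (SE 0.47) and 5.23 (SE 0.52) and Rps7 by 5.49 (SE 0.45) and 5.05 (SE 0.49) in the authors' deposited tables for BAF250A and BRD9. In the 5 members with little shared sequence the medians were 0.64 and 0.08 and the calls were lost (adjusted cameraPR p of 0.0674 and 0.195). Annotated pseudogenes moved the other way, with 337 of 462 lower with BAF250A (median -3.81) and 322 of 479 with BRD9 (median -3.59), against all other genes by Fisher's exact test with two-sided p of 1.8e-156 and 2.1e-221. Among protein-coding genes with a mean of 100 or more and at least 80% of their words shared, 61.8% were lower with BAF250A and 55.3% with BRD9, and among those with 20 to 50% shared, 33.8% and 25.5% were higher. Among those with under 5% shared, 12.4% were higher and 10.7% lower with BAF250A, and 4.83% and 3.71% with BRD9.

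**Figure D3:**
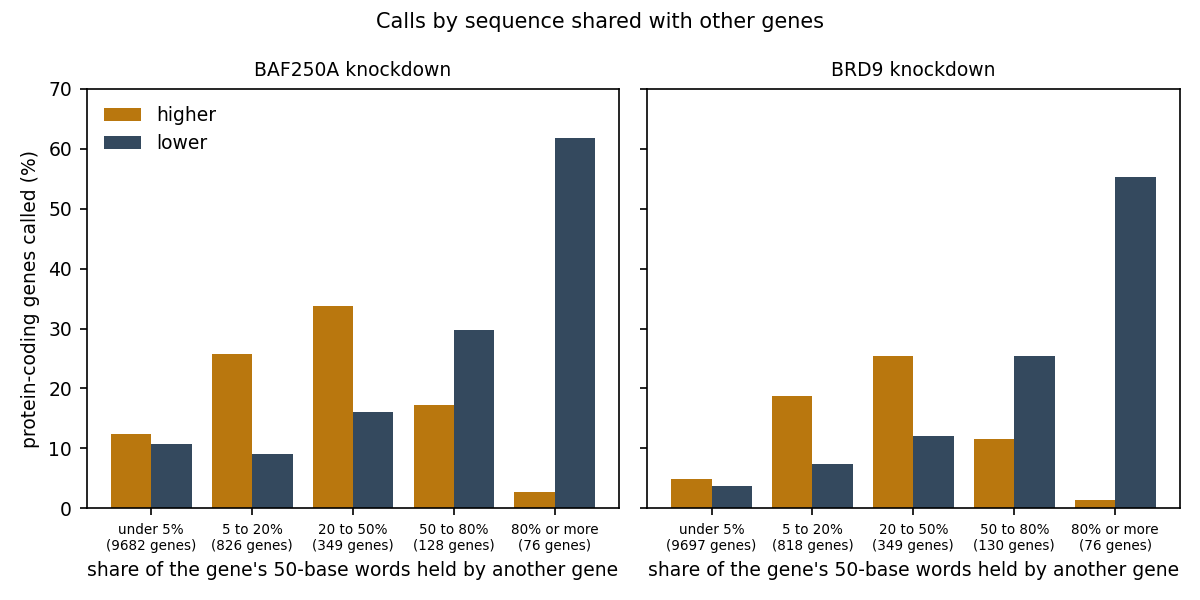
Percent of protein-coding genes with a mean normalized count of 100 or more that were called higher (orange) or lower (dark blue) in each knockdown (vertical axis), by the percent of the gene's 50-base words that another gene also holds (horizontal axis, number of genes below each bin). Calls of higher genes peak at 20 to 50% shared words (33.8% with BAF250A), and calls of lower genes at 80% or more (61.8%).

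The control libraries also stood apart from the knockdown libraries in their lowest counts, and each group of genes described above was compared with these same controls. Among genes with reads and a mean below 3, the number of reads was even in 57.0% and 57.2% of genes in the 2 control libraries and in 72.2% and 81.2% in the knockdown libraries of the BAF250A table. The BRD9 table gave 56.9% and 56.6% in the controls and 81.1% and 78.8% in the knockdowns. Reads in controls and in no knockdown library were found for 3519 such genes and the reverse for 294 in the BAF250A table, and for 3344 and 244 in the BRD9 table. The controls also had the larger size factors, 1.58 and 1.09 against 0.801 and 0.773 in the BAF250A table. How much of these numbers of genes came from depth was not tested. Pseudogenes took 3.17% of the implied control counts and 0.326% of the implied counts in BAF250A knockdown. The control libraries cancel in the difference between knockdowns. The knockdown libraries also differed among themselves, with 72.2% and 81.2% even numbers in the BAF250A libraries, and such differences do not cancel there.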

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

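The tests of even read numbers, of histone genes, of the control libraries' part in the muscle pattern and of an interferon response in the controls alone were chosen only after the result was seen, as were the restriction of lists and counts to genes with little shared sequence and the split of ribosomal protein genes by copies. The results below were picked out because the effects of the 2 knockdowns differed by a test of the difference itself.

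The muscle lists differed between the knockdowns, with median differences (BAF250A minus BRD9) of -3.38 for sarcomere, -2.48 for excitation-contraction coupling and neuromuscular junction, -1.39 for myoblast fusion, -0.88 for myogenic regulators and -0.78 for muscle energy metabolism. Counting of the control libraries would not by itself give a difference between the knockdowns, since the controls cancel there. In that test 75.6% of the measured sarcomere genes were lower with BAF250A. This is the same difference by which the muscle lists were picked out, so it is not separate evidence. Reads shared with near-identical copies are argued against by the sarcomere genes with under 5% shared words, whose median difference was -3.26. Copies that differ more from the gene are not covered by this measure. A need for the BAF form in muscle gene expression that the ncBAF form does not share is a candidate explanation and remains a hypothesis. A difference between the stable lines unrelated to the target stays open, since the labels give 1 shRNA name per target. Of such differences, only a gain or loss of whole chromosomes between the knockdown lines was tested, with a largest chromosome median of 0.19.

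Ribosomal protein genes were higher and pseudogenes lower in both tables, and the ribosomal list still differed between the knockdowns by a median of 0.51 (0.50 in the 5 members with under 5% shared words, where the call was lost). Reads placed differently among copies could account for part of the increase over scrambled shRNA, since adding the implied means of 55 pseudogene copies, held by 25 of the 38 genes, lowered the median of all 38 from 3.01 to 2.21 (interquartile range 1.01 to 3.16) with BAF250A and from 2.52 to 1.65 with BRD9, and that of the 25 from 3.52 to 1.96 and from 3.05 to 1.36. The 13 genes without a matched copy had medians of 2.57 with BAF250A and 1.96 with BRD9, which the matched copies cannot account for. Some of the 13 still share words with other genes, such as Rpsa at 28.7% and Rpl37 at 14.2%, so copies that were not matched stay open. In neither table did the median of the sums fall as far as the prediction written beforehand required. The spread of the sums keeps the explanation open for the rest. Libraries counted or prepared in different ways are in line with even read numbers, where the lowest knockdown library lay 14.9 percentage points above the highest control library, and more RNA without a poly(A) tail in the controls is in line with 56 replication-dependent histone genes (2 of them with under 5% shared words) at a median of -3.35 with BRD9 and -4.11 with BAF250A. These explanations are confounded with the groups, since all controls stand on one side, so no fold change over the scrambled shRNA is free of them, and no biological explanation was tested.

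Interferon response genes fell in both knockdowns and differed between them by a median of -1.47. Reads shared with near-identical copies are argued against by the members with under 5% shared words, whose median was -4.28 or lower in each table. More diverged copies are not covered by this measure, since Aldoart2, a retrotransposed copy, has 0.31% shared words. A response active in the control libraries alone would leave the knockdowns at a like level, so by itself it does not account for the median difference of -1.47 between them. That difference does not show why the controls were higher. Such a response may still account for the part of the decrease that both tables share, as may libraries counted or prepared in different ways. With 1 control group these cannot be separated from an effect of the knockdowns.

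TGF-beta and YAP targets differed by a median of 1.03 and smooth muscle genes by 1.42, both higher with BAF250A by cameraPR. Matrix genes differed by a median of 0.70. Glycolysis genes differed by a median of 0.80 with 0 of 16 single genes called by the difference z test. The stress response list differed by a median of 0.56, also with 0 of 16 single genes called by that test, and across all genes 1362 had an unadjusted p below 0.05. Cell cycle genes differed by a median of 0.47, a call lost at a correlation of 0.05 (adjusted cameraPR p of 0.214) and with little shared sequence (0.091), and E2f2, the 1 called member, was lower with BAF250A at -2.24 (SE 0.69). In opposite directions 39 genes were called in the authors' deposited tables.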

How the results depend on the processing

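No paired analysis was possible because the tables hold no values per library, and for the same reason a replicate block, leaving out each library, count models of other tools, a fit of 4 libraries alone and an estimated list correlation were not run. The restriction to protein-coding genes with under 5% shared words and the difference test with the summed variance divided by 2 were chosen only after the result was seen. No list or named gene called in the main analysis reversed its direction under the alternatives run. The 4729 genes called with BAF250A became 1565 under Bonferroni adjustment, 693 under an empirical null and 2817 with little shared sequence. The 2483 called with BRD9 became 940, 873 and 949. The restriction to little shared sequence also leaves out genes that are not protein-coding. It moved the balance of calls from 1844 higher and 2885 lower to 1361 and 1456 with BAF250A, and from 879 and 1604 to 496 and 453 with BRD9. Protein-coding genes alone held 1816 and 1958 of the main calls with BAF250A and 870 and 876 with BRD9, so a near-even balance was there before shared words were considered. The 414 genes that differed between the knockdowns became 271 at an adjusted p below 0.01, 271 with a mean of 100 or more, 123 under Bonferroni adjustment, 691 under an empirical null and 1231 with the summed variance divided by 2. The smaller counts at an adjusted p below 0.01 and under Bonferroni adjustment follow from stricter thresholds, and the counts under the empirical null from the robust SD of the scores, which was 2.18 with BAF250A, 1.58 with BRD9 and 0.858 for the difference. The parts of gene kind and shared words in the smaller counts were not tested separately. Of the overlaps, the 648 genes higher in both became 427 at an adjusted p below 0.01 and 319 with little shared sequence, and the 1365 lower in both became 805 with a mean of 100 or more and 347 with little shared sequence, and the cause was not tested. The sarcomere call with BRD9 was lost at a correlation of 0.05 (adjusted cameraPR p of 0.193) and with little shared sequence (0.137), where the median was 0.27 as in the whole list and the cause was not tested. The ribosomal protein calls were lost with little shared sequence, where 5 of 38 members were left (adjusted cameraPR p of 0.0674 with BAF250A, 0.195 with BRD9 and 0.219 for the difference). Their medians were 0.64, 0.08 and 0.50, against 3.01, 2.52 and 0.51 in the whole list, so in the difference the members became fewer and the median hardly moved. With little shared sequence some medians of lists that were not called changed sign, with BRD9 from 0.12 to -0.24 for stress response, 0.05 to -0.10 for cell cycle, 0.36 to -0.06 for other cell types and -0.28 to 0.0018 for osteoblast, and with BAF250A from -0.06 to 0.03 for mitochondrially encoded genes. Medians also moved from 0.32 to 0.09 for cell cycle and from 0.66 to 1.07 for osteoblast with BAF250A, and from 0.26 to 0.89 for osteoblast in the difference. The sarcomere list with BAF250A and in the difference, and the interferon list in all comparisons, kept their calls under every alternative run. Of 366 results of the other lists under an alternative, 344 stayed on their side of the threshold, 12 lost and 10 gained a call. Of the losses, 5 came at a correlation of 0.05 and 2 with little shared sequence. The rank-based test and the fold change as statistic lost 2 each, and centring lost 1. Of 1792 results of named genes under an alternative, 1616 stayed, 167 lost and 9 gained a call. Under the empirical null the calls of Arid1a and Myog with BAF250A and of Brd9 with BRD9 were lost. Centring moved the median of genes with a mean of 100 or more by 0.03 with BAF250A and 0.05 with BRD9, and the share of higher calls by under 10 percentage points. The difference test had a median SE of 0.72 among genes with a mean of 100 or more, and the smallest difference called was 2.08 in size.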

Other observations

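The test of whole chromosomes was planned before its result was seen, and the genes of the first paragraph were chosen after their values were seen.

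Genes called in opposite directions included some signalling genes beside the muscle genes, as well as genes of other kinds, and no list of signalling genes was tested. Nts, which encodes the neuropeptide neurotensin, rose by 6.37 (SE 0.50) with BAF250A and stood at -3.27 (SE 1.11) with BRD9 in the authors' deposited tables. Enpp2, which makes lysophosphatidic acid, stood at 2.91 (SE 0.52) and -1.71 (SE 0.62), the prostaglandin synthase gene Ptgs2 at 1.83 (SE 0.49) and -1.68 (SE 0.62) in the authors' deposited tables. The endothelin gene Edn1 stood at 1.60 (SE 0.58) and -2.09 (SE 0.71) and the neuregulin gene Nrg1 at 1.40 (SE 0.47) and -1.92 (SE 0.57) in the authors' deposited tables. Erbb3, a receptor of neuregulins, moved against Nrg1, at -1.47 (SE 0.55) with BAF250A and 3.28 (SE 0.53) with BRD9 in the authors' deposited tables. The difference z test gave Nts an adjusted p of 1.0e-11, Erbb3 2.1e-07 and Nrg1 0.00070.

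A hypothesis was that the knockdown lines differed by a gain or loss of whole chromosomes. This would shift the difference of all genes on a chromosome. The largest chromosome median was 0.19 on the log2 scale, and no chromosome passed cameraPR with Benjamini-Hochberg adjustment. This argues against a gain or loss between the knockdown lines that shifts the genes of a chromosome by clearly more than 0.19. A gain or loss with a smaller shift is left open. So is a gain or loss in the scrambled line, or one shared by both knockdown lines, since these cancel in the difference.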
